A study of Homo sapiens with 8 samples.

How the data were processed

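Small RNAs were measured in 8 samples of HaCaT cells, an immortalized line of human keratinocytes, with the nanoString nCounter miRNA assay, which counts fluorescent barcodes hybridised to each target without amplification. Per the labels' protocols, cells were transfected with siRNAs and kept at high density before total RNA was extracted with TRIzol. The 4 groups, taken from the sample labels, were control siRNA, siRNA against p72, siRNAs against NF2 and LATS2, and siRNAs against DROSHA and DGCR8, with 2 samples per group. The labels do not say whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

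The deposited table held normalized nCounter signal for 822 rows: 800 human miRNA probes, 5 housekeeping mRNAs, 5 probes for plant and worm miRNAs, 6 negative controls and 6 positive spike-ins. The authors' normalization method is not given in the sources used here, and it was read from the values. In each sample, 100% of the human miRNA and mRNA values of the deposited signal were whole multiples of a single factor within a tolerance of 0.006, so that whole counts could be recovered. The factors ranged from 0.715 in control sample 2 to 2.64 in DROSHA/DGCR8 sample 2. After this scaling the geometric mean over the human miRNA probes was nearly equal in the 8 samples, from 24.6 to 24.8. Control probes, spike-ins and non-human probes had been left as raw counts, and were multiplied by the sample's factor here before any comparison. A scaling that equalises the mean of the panel leaves little room for a shift shared by most probes, and most probes lay near background, so the factor was set largely by dim probes. No probe coordinates or genome build were used.

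Recovered miRNA counts summed to between 22200 in DROSHA/DGCR8 sample 2 and 79643 in control sample 2. Within each group the 2 samples differed by more than counting noise, with a chi-square per degree of freedom of 4.74 to 8.70, so no pair is a single measurement entered again. This does not tell separate cultures from repeat runs of a single RNA, and the samples are counted separately because the labels list them so. A probe was called detected where its mean log2 value over the 8 samples exceeded the mean of the negative controls by 2 SDs, a limit of 4.60 on the log2 scale or a signal of 23.3, and 324 probes passed. Of these, 100 had a mean at least 1 log2 unit above the limit and are called abundant below, and the other 224 are called dim. Among the human probes, 10 detect more than 1 miRNA and carry a joint name.

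The comparisons, tests, miRNA lists, naming rule and most alternatives were fixed before the data were examined. The test was limma 3.58.1 in R 4.3.3 on log2(signal + 1), fitted to all 8 samples as 4 groups, with Benjamini-Hochberg adjustment at 5% over the 324 detected probes. The fit had 4 residual degrees of freedom and a prior of 7.60. Fold changes are on the log2(signal + 1) scale, which understates changes of dim miRNAs. Medians over probes were compared with an exact two-sided permutation test over samples, which cannot go below 0.333 for 2 against 2. Of 28 lists of miRNA families, clusters, cell type markers and RNA classes, 18 had at least 3 detected members and were tested with fry and camera, the latter with a preset correlation of 0.01 and with an estimated correlation. Correlations between knockdowns, which share their controls, were set beside 1000 simulated draws of unchanged groups, and overlaps beside 100.

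Named miRNAs followed a fixed rule. Per knockdown, these were the 12 largest falls and 8 largest rises past 5% without overlap of samples, or, where fewer than 5 passed, the 5 largest each way given as values only. The most abundant member of each tested list, the 5 RNAs with the highest mean, and every detected RNA of the list that does not need the Microprocessor were added. A few miRNAs outside the rule are marked where they appear.

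The test was checked on 20 simulated draws of all 8 samples, made from probe means over the 8 samples and the spread of the fit. In each draw 60 miRNAs were lowered in the DROSHA/DGCR8 samples, among a median of 312.5 tested. Noise was drawn separately for each probe, so the rates do not cover shifts shared by the probes of a sample. For the DROSHA/DGCR8 comparison limma recovered 39.2% of 2-fold, 72.1% of 3-fold and 96.6% of 4-fold changes, and called 0.5% of unchanged miRNAs. The first 3 shares are of the 296, 251 and 232 changed miRNAs that stayed detected. Changed miRNAs that dropped below the detection limit were left out, so the share found of all planted changes was lower. Alternatives were other scalings, another pseudocount of 10, background subtraction, other filters, a trended and robust variance, a fit to the 2 groups alone, the replicate number as a block, and each of the 8 samples left out in turn. Chosen after the data were seen were spike-in scaling, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered counts, a fit without 2 doubted samples, the abundant set under every setting, and a comparison of the 6 knockdown samples with the 2 controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.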

Results

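Levels of 800 human miRNAs were measured in HaCaT keratinocytes after transfection of control siRNA or of siRNAs against 3 sets of targets. DROSHA and DGCR8 form the Microprocessor, the nuclear complex that cuts primary miRNA transcripts. The RNA helicase p72, also known as DDX17, is a cofactor of that complex. NF2 and LATS2 are upstream members of the Hippo pathway, which restrains growth at high cell density. Each group had 2 samples, and recovered miRNA counts were 60487 and 79643 in the control, 52191 and 22200 after DROSHA/DGCR8 siRNA, 51477 and 47742 after p72 siRNA, and 44602 and 41227 after NF2/LATS2 siRNA. The panel measured no mRNA of DROSHA, DGCR8, DDX17, NF2 or LATS2, so the knockdowns themselves were not checked here.

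The 5 RNAs with the highest mean signal were miR-4454, the joint probe miR-106a-5p+miR-17-5p, miR-20a-5p+miR-20b-5p, miR-19b-3p and miR-92a-3p. The mean over the 8 samples was 4273 for miR-4454, 4220 for miR-106a-5p+miR-17-5p, 2106 for miR-19b-3p and 1587 for miR-92a-3p. Most of these belong to the miR-17~92 cluster and its paralogs, known as growth-promoting miRNAs. Samples of a group correlated across detected miRNAs at Pearson's r of 0.936 in the control, 0.929 after DROSHA/DGCR8 siRNA, 0.940 after p72 siRNA and 0.944 after NF2/LATS2 siRNA, where miRNAs are not independent replicates. Control sample 1 stood apart, with a mean r of 0.862 with the samples of other groups against 0.904 to 0.935 for the remaining samples. Its housekeeping mRNAs had a normalized geometric mean of 1450, near the 1469 of DROSHA/DGCR8 sample 2, against 625 in control sample 2 and 513 to 1089 in the others.

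After siRNA against DROSHA and DGCR8, abundant miRNAs were mostly lower than in the control by sign, while no single miRNA passed 5% in limma. Over all detected miRNAs the median log2 fold change was -0.074 after DROSHA/DGCR8, -0.081 after p72 and -0.03 after NF2/LATS2 siRNA. The exact permutation test on the sample medians gave p = 0.667, 0.333 and 0.667 in the same order. The authors' scaling, which equalised the mean of the panel, leaves little room for a shift of most probes. These values therefore do not test for a general fall. The results on the abundant set were chosen after the data were seen. Among the 100 abundant miRNAs 81 had a lower group mean. The median log2 fold change of the 100 was -0.89, or 1.85-fold lower (-0.58 without DROSHA/DGCR8 sample 1). In 59 of them both knockdown samples lay below both controls, where chance gives 16.7 on average. That average does not allow for probes of a sample shifting together. Over the sample medians of the abundant set the exact permutation test gave p = 0.333, the lowest it can give, in each of the 3 knockdowns. The 224 dim miRNAs had a median of 0.04, which the scaling, set largely by dim probes, keeps near 0. The lowest values were those of miR-197-3p at -1.89 (SE 0.42), let-7g-5p at -1.84 (SE 0.45), miR-93-5p at -1.82 (SE 0.39), miR-15a-5p at -1.77 (SE 0.44) and miR-196a-5p at -1.76 (SE 0.37), each with a limma adjusted p of 0.0686. The signal of miR-93-5p was 536 ± 194 (SD, n = 2) against 1910 ± 777 in the control (SD, n = 2).

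The highest values after DROSHA/DGCR8 siRNA, none past 5%, were 2.54 for miR-1253, 1.64 for miR-1290, 1.48 for miR-144-3p, 1.40 for miR-155-5p and 1.07 for miR-517a-3p. The value for miR-1253 rested on control sample 1, in which 1 count was recovered against 47 in control sample 2. Among list members, miR-106a-5p+miR-17-5p had a log2 fold change of -1.55, miR-15b-5p -1.74, miR-29b-3p -1.69, miR-107 -1.46, let-7a-5p -1.37 and miR-125a-5p -1.26. By contrast miR-21-5p, an abundant keratinocyte miRNA, had 0.48 and miR-720, a fragment of a tRNA, 0.28, neither past 5%. Of the 7 detected RNAs that do not need the Microprocessor, such as mirtrons and RNAs with capped precursors, 5 were lower by sign and the median was -0.05. Their values were -0.27 for miR-320a, 0.03 for miR-320e, -1.34 for miR-484, -0.04 for miR-1226-3p, -0.05 for miR-1233, -0.32 for miR-1234 and 0.06 for miR-1238. Only 2 of the 7, miR-484 and miR-1234, were abundant. The others were dim, and dim miRNAs as a whole had a median of 0.04, so their values near 0 do not set them apart.

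Of the miR-17~92 list all 9 detected members were lower by sign after DROSHA/DGCR8 siRNA, with a median of -1.14. All 9 were abundant, and in the abundant set 81 of 100 were lower by sign with a median of -0.89. None passed over all miRNAs and 7 were lower when adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 0.000515) but not otherwise (adjusted p = 0.893 with an estimated correlation), and fry passed none of the 18 lists, with 2 at an unadjusted p under 0.05. Camera ranks a list against all other detected miRNAs, which were mostly dim. The camera pass therefore does not separate the list from abundant miRNAs as a whole. All 6 members of the miR-15/16 family, which restrains the cell cycle, were lower by sign with a median of -0.86, and 2 were lower when adjusted over the list alone. For let-7 and miR-98, known to repress growth genes, 4 of 7 members were lower by sign, the same 4 when adjusted over the list alone, with a median of -1.02 and a mean of -0.69.

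At an unadjusted p under 0.05, limma gave 65 lower and 15 higher miRNAs after DROSHA/DGCR8 siRNA. Chance gives 16.2 in all on average, which again leaves out shifts shared by the probes of a sample. The smallest adjusted p was 0.0686. On the recovered counts edgeR called 0 with the authors' factors and 24 with TMM, and DESeq2 called 48. The median log2 fold change of the abundant set was -0.653 without control sample 1 and -1.145 without control sample 2.

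**Figure D1:**
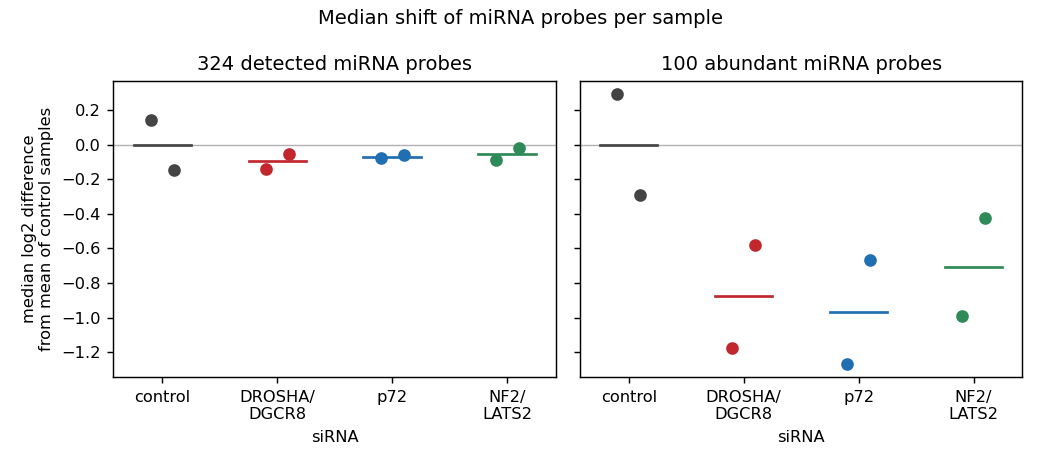
Median log2 difference of each sample from the mean of the control samples (y axis) by siRNA (x axis), over the 324 detected miRNA probes on the left and the 100 abundant probes on the right. Points are samples and lines the mean of the 2 samples of a group; over abundant probes the knockdown samples lie between -1.27 and -0.42 and the controls at -0.29 and 0.29.

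After p72 siRNA, 29 miRNAs fell and none rose at 5% in limma. Folds ranged from 2.31-fold to 5.41-fold lower, with a median of 3.18, and in all 29 both knockdown samples lay below both controls. The fall of miR-197-3p was the largest, from 445 ± 264 (SD, n = 2) to 75.4 ± 22.6 (SD, n = 2), a log2 fold change of -2.44 (SE 0.42, adjusted p = 0.0163). The related miR-374a-5p and miR-374b-5p fell with -2.34 (SE 0.39, adjusted p = 0.0163) and -2.15 (SE 0.50, adjusted p = 0.0262). Next came miR-1180 at -2.15, miR-15b-5p at -1.95, miR-196b-5p at -1.90, miR-196a-5p and miR-25-3p at -1.84, miR-15a-5p at -1.83, let-7g-5p at -1.82, miR-93-5p at -1.78 and miR-32-5p at -1.77. The miR-196 pair lies in the HOX clusters.

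Most calls after p72 siRNA, 27 of 29, were among the abundant miRNAs, of which 84 of 100 were lower by sign with a median log2 fold change of -0.95, or 1.94-fold lower. The dim miRNAs had a median of 0.02, which the scaling again keeps near 0. All 9 detected members of the miR-17~92 list were lower by sign with a median of -1.54. Of these 4 fell over all miRNAs and 8 when adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 6.36e-05) and not with its own (adjusted p = 0.769 with an estimated correlation), and fry passed none of 18 lists, with 4 at an unadjusted p under 0.05. All 9 members were abundant, so the camera pass does not separate the list from abundant miRNAs as a whole. In the miR-15/16 family 2 of 6 fell, also when adjusted over the list alone, and in the miR-99/100 and miR-125 families 1 of 5 fell, and 3 when adjusted over the list alone.

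Several abundant miRNAs did not pass after p72 siRNA, among them miR-106a-5p+miR-17-5p at -1.57 (adjusted p = 0.0600), miR-19b-3p at -1.30, miR-92a-3p at -1.11, let-7a-5p at -1.29, miR-29b-3p at -1.40, miR-96-5p at -1.05 and miR-27b-3p at -0.97. The list of miRNAs reported to need p68 or p72 had 3 of 5 detected members lower by sign, a median of -0.26 and a mean of 0.10, and none passed. Its most abundant member miR-16-5p had -0.91. The mean was raised by miR-143-3p, a member named after its values were seen, which had 2.25 and 1 recovered count in control sample 1. Values near 0 were found for miR-720 at -0.01 and miR-4454 at -0.05, and miR-21-5p had 0.23. The 7 RNAs that do not need the Microprocessor had a median of -0.08, from -0.56 for miR-484 to 0.55 for miR-1238, with -0.23 for miR-320a, -0.39 for miR-320e, 0.40 for miR-1226-3p, 0.01 for miR-1233 and -0.08 for miR-1234.

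The count after p72 siRNA was 0 without control sample 1, 57 without control sample 2 (46 lower, 11 higher), 4 without p72 sample 1 and 0 without p72 sample 2. With housekeeping mRNA scaling and after quantile normalization it was 1, a higher miRNA in each. It was 2 with spike-in scaling, 0 with top-100 scaling and 0 after background subtraction. Scaling on RNAs that do not need the Microprocessor gave 51 (50 lower, 1 higher). Only 2 of the 7 RNAs behind this scaling were abundant, so it rests largely on dim probes.

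**Figure D2:**
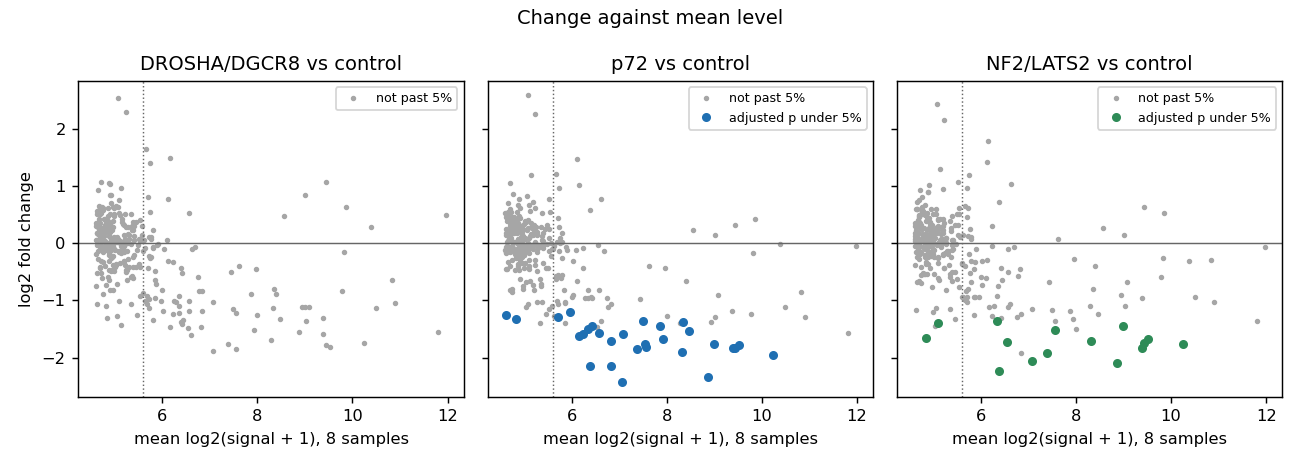
Log2 fold change against the control (y axis) by mean log2(signal + 1) over the 8 samples (x axis) for the 324 detected miRNAs in each knockdown. Coloured points passed 5% in limma (0, 29 and 15 miRNAs), grey points did not, and the dotted line marks the lower limit of the abundant set; the medians right of it are -0.89, -0.95 and -0.70.

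After NF2/LATS2 siRNA, 15 miRNAs fell and none rose at 5%, from 2.58-fold to 4.72-fold lower with a median of 3.32. The largest fall was that of miR-1180, from 231 ± 67.8 to 49.7 ± 22.6 (SD, n = 2 each), with a log2 fold change of -2.24 (SE 0.47, adjusted p = 0.0337). Falls of similar size were seen for miR-374a-5p at -2.10, miR-197-3p at -2.05 and miR-196a-5p at -1.92. Further down were miR-25-3p at -1.83, miR-15b-5p at -1.76, miR-15a-5p at -1.75, miR-324-5p at -1.73, miR-196b-5p at -1.71, miR-93-5p at -1.67, miR-362-5p at -1.66 and miR-32-5p at -1.51. Of the 15 calls 13 were in the abundant set, in which 80 of 100 miRNAs were lower by sign and the median was -0.70, or 1.63-fold lower. It was -0.47 without control sample 1 and -0.42 without NF2/LATS2 sample 1. The dim miRNAs had a median of 0.08, also kept near 0 by the scaling.

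By list, 3 of the 9 miR-17~92 members fell after NF2/LATS2 siRNA and 6 when adjusted over the list alone, with a median of -1.24 and 9 of 9 lower by sign. In the miR-15/16 family 2 of 6 fell and 3 when adjusted over the list alone, with a median of -0.98. Both lists passed camera with the preset correlation, at adjusted p = 0.00086 for miR-17~92 and adjusted p = 0.0313 for miR-15/16, and neither did otherwise (adjusted p = 0.860 for both with an estimated correlation). All 9 miR-17~92 members and 4 of the 6 miR-15/16 members were abundant. The camera passes therefore do not separate these lists from abundant miRNAs as a whole. No list passed fry, with 2 of 18 at an unadjusted p under 0.05. Members that did not pass included miR-125a-5p at -1.49, miR-106a-5p+miR-17-5p at -1.36, let-7a-5p at -1.11, miR-29b-3p at -1.10 and miR-92a-3p at -0.95. The value of miR-144-3p, an erythroid miRNA, was 1.79 (adjusted p = 0.0866). The RNAs that do not need the Microprocessor had a median of 0.30 and 3 of 7 lower by sign, with 0.35 for miR-320a, -0.24 for miR-320e, -0.67 for miR-484, 0.67 for miR-1226-3p, -0.21 for miR-1233, 0.30 for miR-1234 and 0.51 for miR-1238. The values were 0.27 for miR-21-5p and -0.31 for miR-720.

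The count after NF2/LATS2 siRNA was 0 without control sample 1, 48 without control sample 2 (35 lower, 13 higher), and 0 without either NF2/LATS2 sample. It was also 0 with housekeeping mRNA, spike-in, top-100 or quantile scaling, after background subtraction and with no filter on dim probes, and 36 after median centring.

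**Figure D3:**
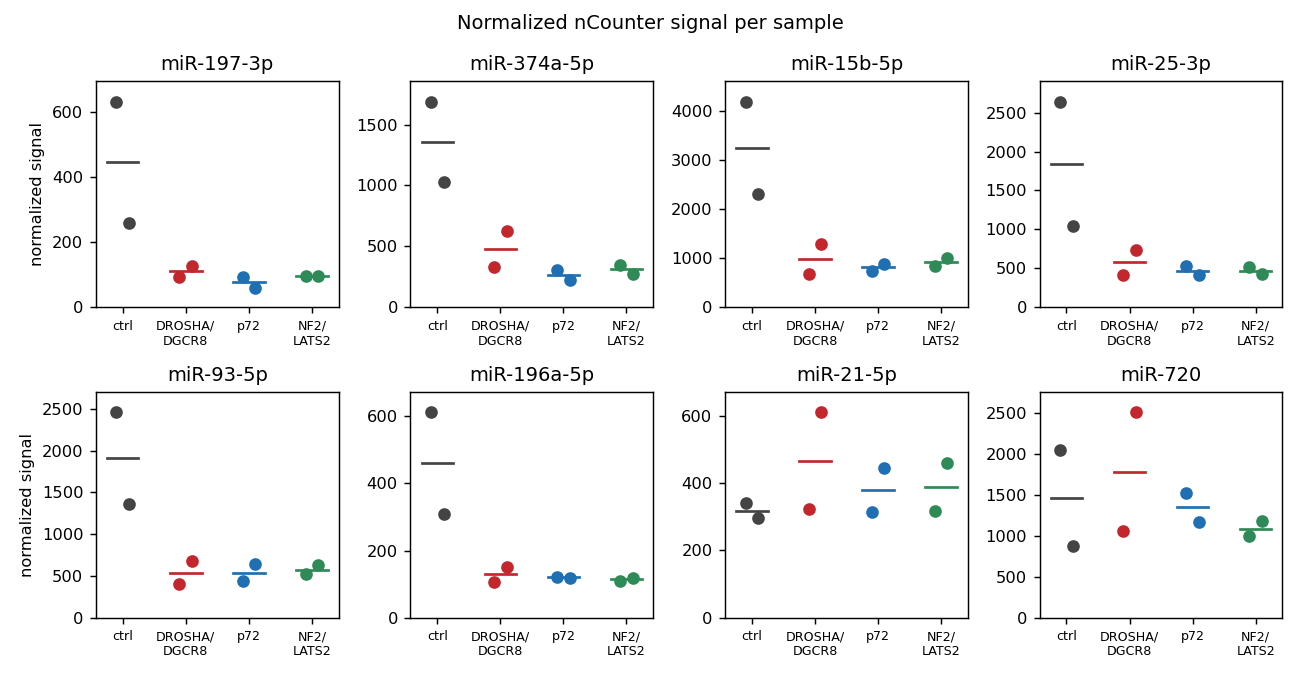
Normalized nCounter signal (y axis, linear from 0) of 8 RNAs in each sample by siRNA (x axis); points are samples and lines the means of 2 samples. For miR-197-3p the controls read 631 and 258 and the knockdown samples 59.5 to 127, whereas miR-21-5p read 339 and 297 in the controls and 313 to 610 in the knockdown samples.

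Whether NF2/LATS2 siRNA acted on the same miRNAs as p72 or DROSHA/DGCR8 siRNA was asked by setting the knockdowns beside each other. No miRNA differed at 5% between any pair in limma, with 12 at an unadjusted p under 0.05 for NF2/LATS2 against DROSHA/DGCR8, 1 for NF2/LATS2 against p72 and 4 for p72 against DROSHA/DGCR8, where chance gives 16.2 in each. For an abundant miRNA the 95% interval of such a difference had a median width of 0.86 log2 units to either side, or 1.82-fold, before any adjustment. The largest differences among abundant miRNAs were 1.16, 0.95 and 1.31 log2 units in the same order, and these did not pass either. Of the 15 miRNAs that fell after NF2/LATS2 siRNA, 13 also fell after p72 siRNA, where independent lists would share 1.34 and simulated unchanged groups with the same controls shared 0. The former leaves out the shared controls and the latter the effects, so neither gives the overlap that lists of this length would have by chance. These were miR-15a-5p, miR-15b-5p, miR-18a-5p, miR-25-3p, miR-32-5p, miR-93-5p, miR-196a-5p, miR-196b-5p, miR-197-3p, miR-362-5p, miR-374a-5p, miR-590-5p and miR-1180, of which miR-18a-5p and miR-590-5p were named after their values were seen. The shared number was 0 without control sample 1 and 32 without control sample 2. Leaving out NF2/LATS2 sample 1, NF2/LATS2 sample 2 or p72 sample 2 also gave 0, and leaving out p72 sample 1 gave 4.

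Across the 324 miRNAs, which are not independent replicates, log2 fold changes of NF2/LATS2 and p72 correlated at r = 0.925 (rho = 0.864), those of p72 and DROSHA/DGCR8 at r = 0.878 (rho = 0.819), and those of NF2/LATS2 and DROSHA/DGCR8 at r = 0.836 (rho = 0.768). Unchanged groups simulated against the same controls gave a mean r of 0.449, 0.454 and 0.455, with the upper limit of 95% of draws at 0.963 or above. The covariance was 0.463, 0.438 and 0.398 against simulated means of 0.0798, 0.0799 and 0.0788. With a separate control sample for each knockdown r was 0.51 to 0.66, and as each side then has 1 control, part of the excess may come from the shared controls. The smaller covariance of the 2 assignments was 0.343, 0.305 and 0.271 in the same order. In simulated unchanged groups the upper limit of 95% of draws was 0.231, 0.239 and 0.230, and 0.8%, 0.9% and 1.7% of draws reached the observed value. The simulation used a spread pooled over the 4 groups, while the control pair differed more than any other over detected miRNAs. Its limits and shares may thus be too low.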

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

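Apart from the human miRNAs, 5 housekeeping mRNAs and 5 non-human probes were compared with the control in the 3 knockdowns, which makes 30 comparisons. In 4 of them both knockdown samples lay above both controls, where chance gives 5. The only such probe above the detection limit was ACTB after NF2/LATS2 siRNA, a signal outside the main measurement that was 1.39 times the control mean, with 448 and 475 against 430 and 235. No explanation was tested for it.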

How the results depend on the processing

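The results on spike-in scaling, edgeR, DESeq2, the fit without 2 doubted samples and the abundant set were chosen after the data were seen. The 24 named falls that passed 5% were negative under every setting that tested them, which with the stricter filter were 23. Sign changes of miRNAs that did not pass were not counted. Falls were named only without overlap of samples, so leaving out samples could not change their sign and does not test it. They were also picked as the largest falls in these same data, so a kept sign under other settings is a weak test. Many of the 24 are the same miRNA after p72 and NF2/LATS2 siRNA, set against the same controls, so they are not separate results. The number of calls moved with the control samples and with the scaling. Where no value below shows it, the cause was not tested. With a single sample left in a group, that sample is assumed to vary like the other groups. The settings meant for a table of raw counts were not run as such, since the table did not hold them. Depth limits the dim miRNAs most, since DROSHA/DGCR8 sample 2 had a median of 8 recovered counts per probe and a factor of 2.64.

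Leaving out each sample in turn gave 0 to 40 calls after DROSHA/DGCR8 siRNA, 0 to 57 after p72 siRNA and 0 to 48 after NF2/LATS2 siRNA, with 0 to 0 in each comparison between knockdowns. The median over detected miRNAs ranged from -0.236 to -0.013, from -0.227 to -0.004 and from -0.129 to 0.032 in the same order. For NF2/LATS2 against DROSHA/DGCR8 it ranged from -0.202 to 0.122, for NF2/LATS2 against p72 from 0.014 to 0.136, and for p72 against DROSHA/DGCR8 from -0.225 to 0.067. The correlation of NF2/LATS2 with DROSHA/DGCR8 ranged from 0.675 to 0.911, that with p72 from 0.852 to 0.959, and that of p72 with DROSHA/DGCR8 from 0.696 to 0.933. Shared falls ranged from 0 to 29, 0 to 32 and 0 to 29.

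Calls after DROSHA/DGCR8 siRNA, 0 in limma, rose to 29 (24 lower, 5 higher) in a fit to the 2 groups alone, 43 (39 lower, 4 higher) after median centring, 5 (0 lower, 5 higher) after quantile normalization, 10 (6 lower, 4 higher) with scaling on RNAs that do not need the Microprocessor, 29 (26 lower, 3 higher) with the stricter filter, 36 (28 lower, 8 higher) with a trended and robust variance, 24 (20 lower, 4 higher) in edgeR with TMM and 48 (44 lower, 4 higher) in DESeq2.

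Calls after p72 siRNA, 29 lower, became 1 (higher) with housekeeping mRNA scaling, 0 with top-100 scaling, 1 (higher) after quantile normalization, 51 (50 lower, 1 higher) with scaling on RNAs that do not need the Microprocessor, 0 after background subtraction, 13 with no filter, 2 with spike-in scaling and 0 without control sample 1 and DROSHA/DGCR8 sample 2. After NF2/LATS2 siRNA the 15 lower became 36 (35 lower, 1 higher) after median centring, 0 with housekeeping mRNA scaling, 0 with top-100 scaling, 0 after quantile normalization, 49 (48 lower, 1 higher) with scaling on RNAs that do not need the Microprocessor, 0 after background subtraction, 0 with no filter, 26 (24 lower, 2 higher) with the stricter filter, 0 with spike-in scaling, 0 without the 2 doubted samples, 24 (22 lower, 2 higher) in edgeR with TMM and 34 (32 lower, 2 higher) in DESeq2.

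Falls shared by NF2/LATS2 and DROSHA/DGCR8, 0 in limma, were 10 in fits to 2 groups, 30 after median centring, 6 with scaling on RNAs that do not need the Microprocessor, 18 with the stricter filter, 12 in edgeR with TMM and 27 in DESeq2; those of p72 and DROSHA/DGCR8, also 0, were 16, 26, 6, 23, 17 and 31. The 13 shared by NF2/LATS2 and p72 became 28 after median centring, 41 with scaling on RNAs that do not need the Microprocessor, 23 with the stricter filter, 20 in edgeR with TMM, 30 in DESeq2, and 0 with housekeeping mRNA, top-100, quantile or spike-in scaling, background subtraction, no filter, or without the 2 doubted samples. Lists past 5% in fry, 0 otherwise, were 6 after p72 siRNA and 5 after NF2/LATS2 siRNA with scaling on RNAs that do not need the Microprocessor. As only 2 of its 7 probes were abundant, that scaling rests largely on dim probes.

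The median over detected miRNAs shifted with scaling by construction. With top-100 scaling, which equalises the abundant miRNAs themselves, it was 0.677 after DROSHA/DGCR8, 0.891 after p72 and 0.784 after NF2/LATS2 siRNA, and the median of abundant miRNAs turned to 0.05 after p72 and 0.127 after NF2/LATS2 siRNA. Housekeeping mRNA scaling gave 0.153 after p72 and -0.174 after NF2/LATS2 siRNA, and scaling on RNAs that do not need the Microprocessor 0.198 after DROSHA/DGCR8 siRNA. The stricter filter gave -0.889, -0.953 and -0.701, and no filter 0.064 after p72 siRNA. For NF2/LATS2 against DROSHA/DGCR8 it was -0.301 with housekeeping mRNA scaling, -0.401 with scaling on RNAs that do not need the Microprocessor and 0.122 without the 2 doubted samples. For NF2/LATS2 against p72, 0.095 in the main setting, it was -0.285 with housekeeping mRNA, -0.071 with top-100, -0.034 with spike-in and -0.047 with Microprocessor-independent scaling, 0.008 after quantile normalization, 0.012 with no filter and 0.194 with the stricter filter. For p72 against DROSHA/DGCR8 it was 0.155 with top-100 and -0.298 with Microprocessor-independent scaling. The correlation of NF2/LATS2 with DROSHA/DGCR8 was 0.698 after quantile normalization and 0.719 with no filter, and that with p72 0.847 and 0.841.

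Deviations of same-numbered samples from their group means correlated between -0.243 and 0.435 over the 6 pairs of groups, highest for NF2/LATS2 and p72. A correlation over probes misses a shift equal over all probes, so pairing by sample number is not excluded. Over abundant miRNAs the medians of samples 1 and 2 were -1.174 and -0.582 after DROSHA/DGCR8, -1.268 and -0.668 after p72, and -0.994 and -0.421 after NF2/LATS2 siRNA. In the control the order was the reverse, with 0.291 and -0.291. With the replicate block the counts were 0 after DROSHA/DGCR8, 25 after p72 and 20 (18 lower, 2 higher) after NF2/LATS2 siRNA, with 15 shared by the last pair.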

Other observations

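The 4 tests on abundant miRNAs, the comparison of all knockdown samples with the control and the values of single probes were chosen after the result was seen, and the 2 tests on the likeness of the knockdowns were set before. Of those 4, the rules of 3 were changed once their values were seen, and each had first counted against its explanation. For control sample 1 the SE was 0.136 from the knockdown samples alone, for housekeeping mRNA scaling no spread between samples was asked for, and for the RNAs that do not need the Microprocessor any percentile under 50 counted, a limit then moved to 2.5 as the random range was -0.518 to 0.415. Other lists fixed in advance held no call of their own in fry. In all 3 knockdowns the 3 members of the miR-183 cluster and the 4 of the miR-23/27/24 clusters were lower by sign, with medians of -0.71, -0.81 and -0.46 for the former and -0.43, -0.71 and -0.77 for the latter after DROSHA/DGCR8, p72 and NF2/LATS2 siRNA. In the same order medians were -0.84, -1.12 and -0.61 for the miR-29 family, -0.07, -0.63 and 0.02 for the miR-30 family, -0.16, -0.47 and -0.36 for the miR-130 family, -0.44, -0.44 and -0.29 for 11 keratinocyte miRNAs, and -0.46, -0.17 and -0.32 for 7 p53-responsive miRNAs, whose mean was 0.06 after NF2/LATS2 siRNA. Medians of miRNAs reported to need p68 or p72 were -0.10 after DROSHA/DGCR8 and -0.24 after NF2/LATS2 siRNA, with means of 0.23 and 0.22. RNAs since assigned to tRNA, rRNA or vault RNA had medians of 0.17, -0.01 and -0.26, and the miR-99/100 and miR-125 families -0.48, -1.03 and -0.94. The let-7 and miR-98 family had -0.43 and -0.12 after p72 and NF2/LATS2 siRNA.

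Markers of other cell types gave no list past 5%. Medians were 0.11, 0.26 and 0.29 for muscle, -0.21, 0.24 and 0.36 for blood cells, -0.60, -0.95 and -0.64 for neurons and 0.00, -0.11 and 0.07 for pluripotency miRNAs, led by miR-1, miR-144-3p, miR-9-5p and miR-302d-3p. Lists with fewer than 3 detected members had no test. In these miR-148b-3p at -1.37 and miR-10a-5p at -1.46 fell after p72 siRNA, and the joint probe miR-181b-5p+miR-181d at -1.39 fell after NF2/LATS2 siRNA, while miR-148a-3p at -1.39, miR-10b-5p at -0.82 and miR-181a-5p at -0.43 did not pass in the same knockdowns. Not past 5% in any knockdown were miR-221-3p at -1.30, -1.19 and -0.96, its partner miR-222-3p at -0.41, -0.39 and 0.07, miR-26a-5p at -0.50, -0.97 and -0.67, miR-26b-5p at -0.97, -1.07 and -0.80, miR-107 at -1.46, -1.06 and -0.46, miR-126-3p, the endothelial marker, at -1.60, -1.36 and -1.07, and in the miR-200 family miR-141-3p at -0.06, 0.16 and 0.42 and miR-200a-3p at 0.50, 0.62 and 0.35. Of 2 fibroblast and smooth muscle markers, also not past 5%, miR-199a-5p had -0.10, -0.26 and -0.24 and miR-143-3p 2.30, 2.25 and 2.15. No liver marker was detected.

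Set against the control as 6 samples, the knockdowns had 40 lower and 2 higher miRNAs at 5% in limma, the latter being miR-1253 and miR-155-5p. Without control sample 1 the count was 0 and without control sample 2 it was 66 (52 lower, 14 higher). In 67 miRNAs all 6 samples lay below both controls and in 20 above, where chance gives 11.6 each way on average. That average does not allow for probes of a sample shifting together. A plant probe, osa-miR442, had scaled means of 30.3, 25.6 and 34.0 after DROSHA/DGCR8, p72 and NF2/LATS2 siRNA against 56.3 in the control. In control sample 1 a single count was recovered for miR-1253, miR-143-3p and miR-363-3p, against 47, 79 and 56 in control sample 2.

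The first pattern weighed is the lower level of abundant miRNAs in the 3 knockdowns, seen in 6 of 6 samples with an exact permutation p of 0.0714, the smallest that 6 against 2 can give. A scaling factor per sample would move all RNAs of a sample alike, but the gap between abundant miRNAs and the tRNA-derived miR-720 and miR-1260a was lower in the knockdown samples by -0.782 on the log2 scale, just over 2 pooled SDs of 0.382 and resting on 2 reference probes. A high reading of control sample 1 alone stays open: against control sample 2 the 6 medians averaged -0.576, all below 0, but the SE is 0.448 once the spread of a single control sample is included. Less RNA in the knockdown samples is not supported by housekeeping mRNA scaling, which moved the medians from -0.889, -0.953 and -0.701 to -0.757, -0.709 and -0.845 and ended the falls at 5% because the median SE rose from 0.394 to 0.703, but it stays open since the weakest, -0.709, lies within 2 pooled SDs of 0.424. Lower cutting by the Microprocessor may be a candidate explanation. The 7 RNAs that do not need it, most near the floor, lay at the 44.7th percentile of 10000 abundance-matched random lists after DROSHA/DGCR8 siRNA. Their 2 abundant members lay on either side of the abundant median of -0.889, miR-484 at -1.34 and miR-1234 at -0.32. These values leave the explanation open.

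The second pattern is the likeness of the 3 knockdown profiles. A single unequal control is argued against by giving each knockdown its own control sample, since the covariance of fold changes then stayed at 0.682 or more of its former value in both assignments. Chance from the shared controls cannot be told apart by the rule set in advance, which asked for a covariance above every simulated draw. The smallest ratio to the highest draw was 0.377, although 0.6% to 0.9% of draws reached the observed covariance. With separate controls 0.8% to 1.7% of draws reached the smaller observed covariance. These shares do not decide the question, since the simulation gave every sample the spread pooled over the 4 groups. Over detected miRNAs the control pair differed most, with an SD of difference of 0.673 log2 units against 0.467 to 0.580 in the knockdowns. The simulated covariances may thus be too small. The rule set in advance did not use the separate controls, and the 3 pairs overlap. A shared effect of the knockdowns, or of any active siRNA against the control siRNA, stays an untested hypothesis.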
